A study of Homo sapiens with 30 samples.

How the data were processed

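T47D cells, an established human breast cancer line, were transfected with siRNA at 10 nM, given fresh medium after 48 hours and harvested 48 hours later, per the labels' protocols. Total RNA (1 ug per sample) was depleted of ribosomal RNA, converted to labelled cDNA and hybridised to Affymetrix human exon arrays. There were 5 groups of 3 arrays: a control siRNA against luciferase, and siRNA against the NELF subunits A, B, C and E. The series text calls the 3 arrays of a group technical repeats. P-values therefore measure the spread between repeats, not between separate cultures. Groups and replicate numbers were taken from the labels, and the number of arrays limits the precision of every value.

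The deposited values were on a log2 scale. Per the labels, they were robust multi-array average (RMA) values from the ArrayAssist software for core exons on genome build hg18; its version was not given in the sources used here. A gene-level table held 22011 transcript clusters and an exon-level table held 287329 probe sets, each for the same 15 arrays. Each array's gene-level values, set against the medians of its exon-level probe sets over 13826 genes, correlated best with the exon-level column of the same group and replicate in 15 of 15 cases. Column medians differed between arrays. The deposited values were used as they stand, and other scalings were tried as alternatives. Every value column was used, and no pair of columns was identical.

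Gene symbols came from the platform annotation supplied with the data, updated through a current RefSeq gene table that was used for names only. Of the transcript clusters, 14432 carried 1 symbol, 2408 carried several and 5171 were not listed. Of the probe sets, 261273 carried 1 symbol, 9155 several and 16901 were not listed. The update renamed 22 clusters and 31110 probe sets. Only features with 1 symbol are named, and a feature that is not listed is unnamed here. Chromosomal positions were not used here. Where a symbol had 2 clusters, the brighter was used.

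The tests were run in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. One linear model with a mean for each of the 5 groups was fitted to all 15 arrays with lmFit and eBayes, so that all groups shared one estimate of spread. Contrasts compared each knockdown with control, the mean of the 4 knockdowns with control (the average contrast), and the 6 pairs of knockdowns. A transcript cluster, hereafter a gene, was called at a Benjamini-Hochberg adjusted p below 0.05 over all clusters and a change of at least 1.5-fold. The same thresholds were applied to all probe sets. Exon usage, the change of a probe set relative to the other probe sets of its gene, was tested with limma's diffSplice. It covered 137508 probe sets of 8751 genes, after leaving out probe sets below the 25th percentile of means, genes below the 40th percentile and genes with fewer than 3 probe sets. Target genes without a gene-level cluster of their own were measured as the median of their exon-level probe sets, a departure from the planned gene-level test. NELFB had no probe set under its symbol and was not analysed here.

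The design, the thresholds, the alternatives, the rule for named genes and the gene lists were fixed before the data were examined. The rule named the NELF subunits, and the 12 genes that changed most in all 4 knockdowns in each direction. For each knockdown it named the 6 highest and 6 lowest called genes whose 3 arrays lay beyond all 3 control arrays, and up to 4 genes called against control and against each other knockdown. From each list it named up to 4 called members (6 for DNA replication, mitosis, oestrogen-induced and immediate early genes) and up to 2 bright members that were not called. For exon usage it named up to 10 shared probe sets and up to 3 per knockdown.

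The 25 lists covered DNA replication and S phase, G2/M and mitosis, homologous recombination and crosslink repair, replication-dependent histones, oestrogen-induced genes, immediate early genes, heat shock, p53 targets, interferon-stimulated genes, NF-kB and inflammatory genes, the unfolded protein and ATF4 response, cholesterol synthesis, hypoxia and glycolysis, cytosolic ribosomal proteins, pausing and elongation factors, cell cycle inhibitors, apoptosis regulators, extracellular matrix and TGF-beta response, antigen presentation, lysosome and autophagy, and markers of luminal, basal, mesenchymal, endothelial and leukocyte cells. They were tested in the average contrast and in each knockdown against control with limma's camera at a preset inter-gene correlation of 0.01. P-values were adjusted over the 25 lists in a contrast. The tests were run again with the correlation estimated from the residuals and with fry. List p-values are those of the average contrast unless a knockdown is named. There were 16 genes in more than 1 list. Camera compares a list with all other genes, whereas fry tests whether the members move on balance one way.

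Before use on the real values, the limma tests of genes and probe sets were tested on simulated data with 200 changed genes among the real spreads. For exon usage the simulations followed the main test on the real values. For single knockdowns, limma recovered 4.48% to 10.4% of genes changed 1.5-fold, 43.3% to 52.2% of those changed 2-fold and 78.8% to 86.4% of those changed 3-fold, with 2 to 9 false calls among 22011 genes. For the average contrast the shares were 22.4%, 77.6% and 95.5%. For probe sets, the same 200 changes among 287329 were recovered in no single knockdown contrast at any of the 3 sizes, and 9.09% of the 3-fold changes were recovered in the average contrast, so single probe sets of that size are largely missed. The diffSplice test, simulated for siNELF-C over 137508 probe sets, recovered 30.3% of 3-fold changes with 200 false calls. The same simulated usage test with each probe set's own spread gave 0 false calls and recovered 0 of the 3-fold changes. With 2000 changes diffSplice recovered 37.8% of the 3-fold ones with 358 false calls, and the own spread 5.41% with 4. False calls shared by all 4 knockdowns numbered 6 and 9 under diffSplice in the 2 simulations, and 0 under the own spread. In all of these simulations the noise was independent between genes and between arrays. The real arrays also differed in their whole spread, so the simulated false calls and recovery need not hold for them.

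Comparisons that share control arrays also share their chance values. Unchanged groups were therefore simulated against these controls, and the simulated overlap and correlation are given beside the observed ones. The 3 controls cannot be divided into 2 sets of 2, so part of any excess may come from the shared controls. Alternatives to the main setting were quantile normalization, centring on array medians or 75th percentiles, a replicate block, filters on dim clusters, a fit with only the 2 groups compared, a trended and robust variance, other fold thresholds, limma's treat, gene values as medians of probe sets, a splicing index for exon usage, other set tests, and leaving out each array.

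Further alternatives were chosen after the values were seen. They were leaving out siNELF-B replicates 2 and 3 together, leaving out the siNELF-B group, the interquartile range of each array as a covariate, and each probe set's own spread in the usage test. The gene lists were also run with arrays centred on their 75th percentiles. The pair contrasts, with those of named genes and the counts of genes that differed from control and each other knockdown, were also run under the other scalings and without single arrays, and the correlations without single arrays. A control array held out of the fit was used as the value of an unchanged array, and ESR1 was refitted under each scaling and with the covariate. Array weights were tried and not used, since their estimate did not converge.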

Results

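Negative elongation factor, NELF, is a complex of 4 subunits that holds RNA polymerase II close to promoters. Exon arrays were used to ask which genes and exons change when each subunit is depleted from T47D cells, a luminal, hormone receptor-positive breast cancer line, and which change in common. Control siRNA and siRNA against NELF-A, NELF-B, NELF-C or NELF-E were each represented by 3 arrays, 15 in all. The pairwise correlation of gene-level values within a group was 0.9836 to 0.9895 in the control, siNELF-A, siNELF-C and siNELF-E groups, and 0.9172 to 0.9729 in siNELF-B. Array spread also differed. The interquartile range of log2 values was 3.95 to 4.12 on the control arrays, 3.61 to 3.75 on the siNELF-C arrays, and 3.57, 4.02 and 3.12 on siNELF-B replicates 1, 2 and 3. SiNELF-B replicate 2 correlated more closely with the controls (mean r = 0.9845) than with its own group (0.945), and replicate 3 had a mean r of 0.9323 with all other arrays. Many counts are therefore also given without these 2 arrays, a choice made after the values were seen. SiNELF-B is then a single array, and the other groups supply all of the spread in its tests. No background signal was measured here, so a fold from a level near the 25th percentile of all genes (2.70) may not be that of the transcript. For named genes no fold is given where the levels on both sides lay below 3.901, the 40th percentile of gene means, a choice made after the values were seen.

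The targets were examined first. NELFCD (transcript cluster 3891278), which encodes the NELF-C and NELF-D forms, fell 10.7-fold in siNELF-C cells (log2 change -3.42, SE 0.267, adjusted p = 1.67e-05), from 9.249 ± 0.072 to 5.833 ± 0.195 (SD, n = 3 in each group, limma). In the other knockdowns its log2 changes did not pass the test: -0.66 in siNELF-A (adjusted p = 0.221), -0.64 in siNELF-B (0.136) and 0.39 in siNELF-E (0.55). NELFE, measured as the median of 15 probe sets, fell 6.1-fold in siNELF-E cells (log2 change -2.61, SE 0.222, adjusted p = 2.49e-05), with changes of 0.61, -0.43 and -0.49 that did not pass in siNELF-A, siNELF-B and siNELF-C (adjusted p = 0.196, 0.194 and 0.199). NELFA, also the median of 15 probe sets, measured -0.61 in siNELF-A cells (SE 0.215, adjusted p = 0.176) and -0.06, 0.07 and 0.10 in siNELF-B, siNELF-C and siNELF-E (0.866, 0.872 and 0.931). Without siNELF-B replicates 2 and 3 the NELFA value in siNELF-A was the same and passed (adjusted p = 0.0364). NELFB was not analysed here, so the siNELF-B label has no check at its own target.

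**Figure D1:**
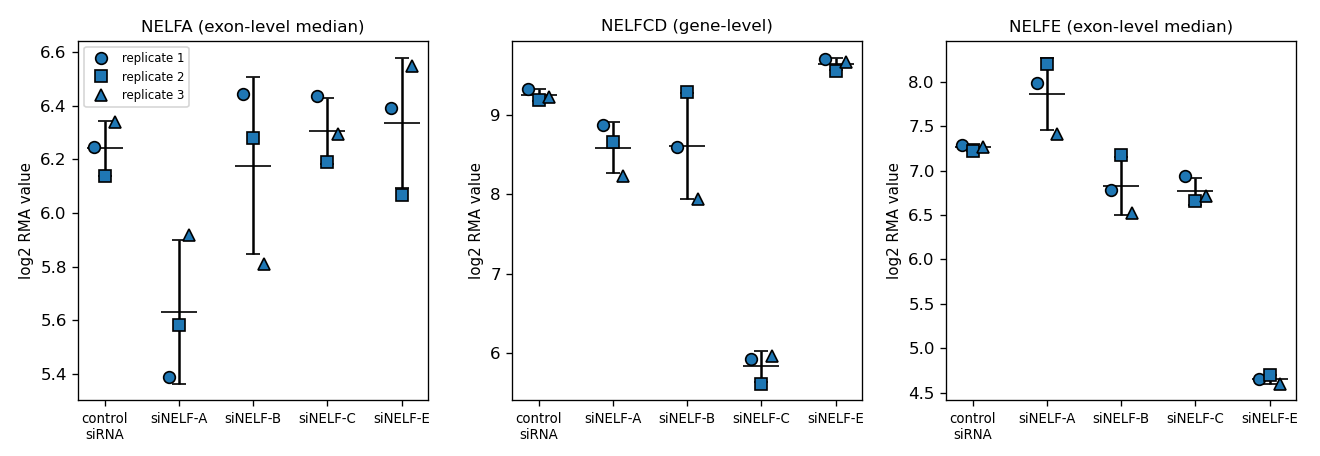
Log2 RMA values of NELFA, NELFCD and NELFE (y axes, which do not start at 0) on the 15 arrays by group (x axis); symbols are replicates, long dashes are group means and bars are SDs (n = 3). NELFCD has a mean of 5.833 in siNELF-C against 9.249 in control, and NELFE 4.65 in siNELF-E against 7.26, while the NELFA values of siNELF-A lie between 5.39 and 5.92 against a control mean of 6.24.

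Interferon-stimulated genes were lower in all 4 knockdowns. IFIT1 (cluster 3257246), an RNA-binding antiviral protein, fell 31.2-fold on average (log2 change -4.97, SE 0.193, adjusted p = 4.78e-08), by 18.9-fold in siNELF-A, 38.4-fold in siNELF-B, 32.5-fold in siNELF-C and 40.2-fold in siNELF-E. MX1, a GTPase that restricts viral replication, fell 14.7-fold, and OAS2, a sensor of double-stranded RNA, fell 11-fold. IFIT3, IFI6, IFITM1, OAS1, OAS3, IFI27, IRF9 and IFIT5 also fell in all 4 knockdowns, with average log2 changes between -3.18 for IFIT3 and -2.12 for IFIT5. DDX60 was called lower in all 4, but at levels too low for a fold (3.689 in control, 1.621 to 1.779 in the knockdowns). IRF9, the DNA-binding part of the factor that drives these genes, fell 4.36-fold (log2 change -2.13, SE 0.138, adjusted p = 2.27e-06). All 12 genes kept their calls in the average contrast when any 1 of the 15 arrays was left out. Of the 38 measured members of the interferon list, 25 fell in the average contrast, and 26 adjusted over the list alone. BST2 and IRF7 did not pass, with log2 changes of -0.94 (adjusted p = 0.0613) and -0.18 (0.468), although BST2 passed without siNELF-B replicate 2 (0.0014) or 3 (0.0166). The list median was -1.40 (camera adjusted p = 1.26e-31; adjusted p = 0.00357 with an estimated correlation), and it was -1.43, -1.52, -1.33 and -1.08 in siNELF-A, siNELF-B, siNELF-C and siNELF-E. In the same 4 contrasts 25, 25, 25 and 21 members fell, and 26, 25, 26 and 25 without siNELF-B replicates 2 and 3. Interferon-stimulated genes made up 20 of the 105 clusters that fell in all 4 knockdowns, of which 80 carried 1 symbol. Fisher's exact test over all 22011 clusters gave p = 1.71e-37. It included clusters without 1 symbol, which could not be list members, and took genes as independent. On siNELF-B replicate 2 the list median was -0.99, compared with -1.54 and -1.95 on replicates 1 and 3.

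Genes of cell division were lower as well. Of 41 mitosis genes, 37 fell in the average contrast, and 40 adjusted over the list alone (median -1.27, camera adjusted p = 9.06e-29; adjusted p = 0.205 with an estimated correlation). FOXM1, a transcription factor of mitotic genes, fell 3.18-fold (log2 change -1.67, SE 0.234, adjusted p = 0.00167), and the mitotic kinesin KIF14 fell 3.57-fold (-1.84, SE 0.3, adjusted p = 0.0042). NUF2, SPC25, KIF11 and HMMR, of the kinetochore and spindle, fell 3.01- to 4.59-fold. NUF2 lost its call without control replicate 3 (adjusted p = 0.0623) and SPC25 without control replicate 2 (0.0771) or 3 (0.145). KIF11 and HMMR lost theirs without any 1 of the control replicates 1, 2 and 3 (adjusted p = 0.106, 0.0959 and 0.145 for KIF11, and 0.0713, 0.0906 and 0.132 for HMMR). ECT2 and CKS2 did not pass (-1.05, adjusted p = 0.0526; -0.68, adjusted p = 0.254) but did without siNELF-B replicate 2 (0.00174 and 0.0391), and ECT2 also without siNELF-B replicate 3 (0.00713). The list median was -0.79 in siNELF-A, -0.90 in siNELF-B, -1.30 in siNELF-C and -2.15 in siNELF-E, where 5, 4, 32 and 38 members were called. The lists were not tested between knockdowns. SiNELF-B replicate 2 stood at -0.10 for this list, against -0.87 and -1.80 on replicates 1 and 3. Without replicates 2 and 3, all 41 members were called on average, 28 on the 1 siNELF-B array left, and 32, 40 and 41 in siNELF-A, siNELF-C and siNELF-E. After quantile normalization the 4 counts were 11, 1, 32 and 40, and with the interquartile range of each array as a covariate they were 12, 0, 23 and 41.

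**Figure D2:**
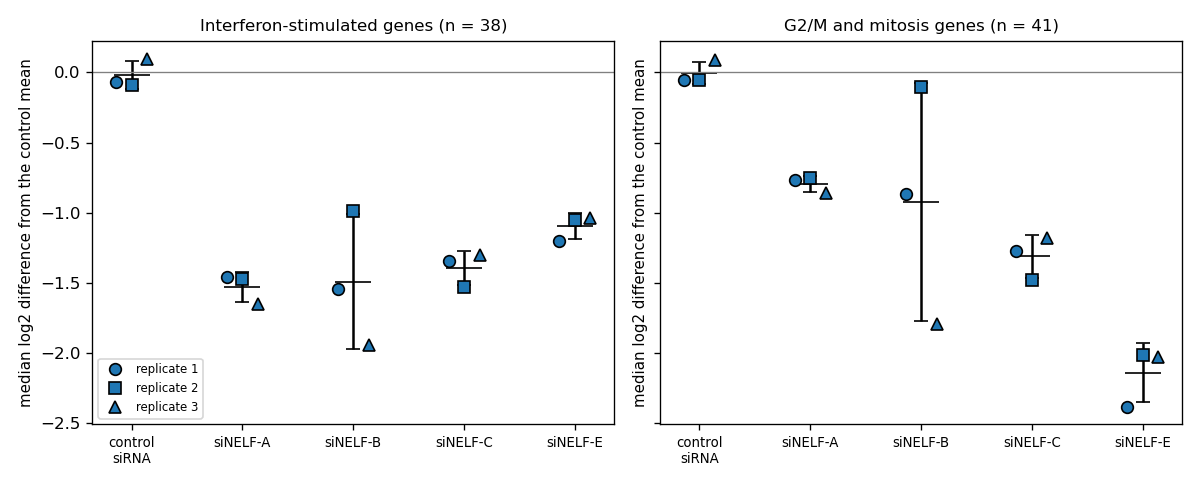
Median log2 difference from the control mean (y axis) over the 38 measured interferon-stimulated genes (left) and the 41 measured mitosis genes (right) on each array, by group (x axis); symbols are replicates, long dashes are group means and bars are SDs (n = 3). All knockdown arrays lie below the controls for the interferon genes, while siNELF-B replicate 2 lies at -0.10 for the mitosis genes and the siNELF-E arrays lie between -2.39 and -2.01.

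DNA replication genes fell too. In this list 30 of 44 measured members fell, and 37 adjusted over the list alone (median -1.05, camera adjusted p = 2.92e-21; adjusted p = 0.205 with an estimated correlation). DTL, which directs the licensing factor CDT1 to degradation, fell 2.96-fold (log2 change -1.57, SE 0.243, adjusted p = 0.0031). TK1, a thymidine kinase of S phase, fell 2.43-fold (-1.28, SE 0.15, adjusted p = 0.000537), and cyclin A2 (CCNA2) fell 2.6-fold (-1.38, SE 0.228, adjusted p = 0.00436). POLE2, CLSPN and MCM10, of the replication fork, fell 2.74-, 2.56- and 2.45-fold. POLE2 lost its call without control replicate 3 (adjusted p = 0.076), CLSPN without control replicate 2 (0.0858) or 3 (0.123), and MCM10 without control replicate 1, 2 or 3 (0.0622, 0.0553 and 0.0835). RPA1 and MCM4 did not pass (-0.62, adjusted p = 0.117; -0.55, adjusted p = 0.0898) but did without siNELF-B replicate 2 (0.0103 and 0.00574). Members lower in siNELF-A, siNELF-B, siNELF-C and siNELF-E numbered 4, 8, 25 and 36, and 35 on average and 19, 25, 36 and 39 in each without siNELF-B replicates 2 and 3. After quantile normalization 23 fell on average and 5, 6, 21 and 38 in each. With the interquartile range of each array as a covariate, an alternative added after the values were seen, 20 members fell in the average contrast and 4, 0, 15 and 39 in each.

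Repair and histone genes fell with them in the average contrast. Of 20 genes of homologous recombination and crosslink repair, 14 fell, and 16 adjusted over the list alone (median -0.89, camera adjusted p = 7.30e-12; adjusted p = 0.208 with an estimated correlation). They included FANCI, of the Fanconi pathway (3.34-fold), and the exonuclease EXO1 (2.79-fold). Repair genes called lower in siNELF-A, siNELF-B, siNELF-C and siNELF-E numbered 0, 3, 12 and 15. BRIP1 and BRCA1 fell 2.96- and 2.65-fold and lost their calls without control replicate 1 (adjusted p = 0.0566 and 0.0567) or 3 (0.076 and 0.0797). NBN and PALB2 did not pass (-0.80 and -0.53) but did without siNELF-B replicate 2 (0.0119 and 0.0231), and NBN also without siNELF-B replicate 3 (0.0437). Of 41 replication-dependent histone genes, 20 fell, and 26 adjusted over the list alone (median -0.97, camera adjusted p = 5.15e-12; adjusted p = 0.205 with an estimated correlation). H4C3 fell 3.05-fold and H2AC4, H2BC4 and H3C1 fell 3.51-, 3.2- and 3.37-fold. All 4 lost their calls without control replicate 3 (adjusted p = 0.0523, 0.106, 0.153 and 0.22), as did H2AC4, H2BC4 and H3C1 without control replicate 1 (0.08, 0.0788 and 0.123) and H2BC4 and H3C1 without control replicate 2 (0.0564 and 0.0857). H3C1 also lost it without siNELF-A replicate 3, siNELF-B replicate 1, siNELF-C replicate 2 or 3, or siNELF-E replicate 3 (0.0513 to 0.0579). H4C8 and H2AC6 did not pass (-0.46 and -0.36). Histone genes called lower in siNELF-A, siNELF-B, siNELF-C and siNELF-E numbered 11, 1, 13 and 20. Histone genes are near-identical copies, so their probes are uncertain in separating them. Without siNELF-B replicates 2 and 3, 16 repair and 29 histone genes fell on average, after quantile normalization 12 and 18, and with the interquartile range as a covariate 7 and 15.

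The oestrogen receptor and genes it induces also fell. ESR1, which encodes oestrogen receptor alpha, fell 2.2-fold on average (log2 change -1.14, SE 0.143, adjusted p = 0.000829) and was called in each of the 4 knockdowns, between -0.89 in siNELF-B and -1.38 in siNELF-C. The siNELF-B call of ESR1 was lost after quantile normalization (-0.40, adjusted p = 0.0672), with arrays centred on their 75th percentiles (-0.42, 0.0705) and with the interquartile range as a covariate (-0.47, 0.125), while the other 3 were kept. Of 28 oestrogen-induced genes, 11 fell, and 14 adjusted over the list alone (median -0.58, camera adjusted p = 3.20e-09; adjusted p = 0.205 with an estimated correlation). Members called lower numbered 10, 4, 11 and 8 in siNELF-A, siNELF-B, siNELF-C and siNELF-E, with 1 higher in siNELF-A and 1 in siNELF-E. RERG, a growth-restraining small GTPase, fell 3.37-fold (-1.75, SE 0.213, adjusted p = 0.000671). The chemokine CXCL12 and the IGF-binding protein IGFBP4 fell 2.02- and 1.9-fold on average, but lay near the controls in siNELF-B. CXCL12 measured 9.202, 9.692 and 8.808 there, against 9.109, 9.149 and 9.246 in control. IGFBP4 measured 9.609, 9.724 and 9.462 there, against 9.835, 9.518 and 9.64. The transcription factor MYB, the secreted STC2 and the progesterone receptor PGR fell 2.96-, 2.25- and 1.91-fold. All 3 lost their calls without control replicate 3 (adjusted p = 0.0709, 0.0745 and 0.12), and PGR also without control replicate 1 (0.0993) or 2 (0.0712). XBP1 and CA12 did not pass (-0.33, adjusted p = 0.0806; -0.21, adjusted p = 0.343). Without siNELF-B replicates 2 and 3, 14 of the 28 genes fell, after quantile normalization 6, and 7 with the interquartile range as a covariate. In the luminal list ESR1 was the 1 called gene of 17 in the average contrast (camera adjusted p = 0.256), and the keratins KRT19 and KRT8 measured -0.02 and 0.10. Luminal genes called lower numbered 4, 1, 4 and 1 in siNELF-A, siNELF-B, siNELF-C and siNELF-E, with 1 higher in siNELF-E. In siNELF-C the list was lower (median -0.33, camera adjusted p = 0.00887), but not with an estimated correlation (0.485). Its median in siNELF-E was 0.09 (camera adjusted p = 0.1).

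Antigen presentation genes, which load peptides onto class I molecules, fell in part. Of 16 measured members 7 fell, and 7 adjusted over the list alone (median -0.41, camera adjusted p = 0.00477; adjusted p = 0.205 with an estimated correlation). Members called lower numbered 6, 3, 2 and 1 in siNELF-A, siNELF-B, siNELF-C and siNELF-E. On average the immunoproteasome subunit PSMB8 fell 2.94-fold, the peptide trimmers ERAP2 and ERAP1 fell 1.91- and 1.89-fold, and TAPBP fell 1.73-fold. ERAP2, ERAP1 and TAPBP were lowest in siNELF-A. ERAP1 measured 4.277, 4.176 and 3.983 there and 6.261, 6.508 and 6.594 in siNELF-E, against 6.286, 6.449 and 6.606 in control. PSMB8 lost its call without control replicate 1 (adjusted p = 0.0504) or 3 (0.0884). ERAP2, ERAP1 and TAPBP lost theirs without control replicate 1 (0.0696, 0.0717 and 0.103), 2 (0.0762, 0.0906 and 0.057) or 3 (0.161, 0.15 and 0.0948). B2M and HLA-E did not pass (-0.28 and -0.24). Without siNELF-B replicates 2 and 3 the count stayed at 7, after quantile normalization 3 members fell, and 2 with the interquartile range as a covariate.

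Across all genes, far more fell than rose. Called against control were 731 genes in siNELF-A, 967 in siNELF-B, 1369 in siNELF-C and 1206 in siNELF-E, of which 14.9%, 4.65%, 14.8% and 26.3% were higher than in control. The repeats are technical, so these counts cannot separate an effect of the siRNA from a difference between cultures. The siNELF-B count ranged from 87 to 7450 when single arrays were left out. After quantile normalization the shares that were higher were 33.2%, 30.9%, 35.3% and 41.4%. Median centring gave 26.5%, 17.6%, 25.6% and 39.5%. Centring on 75th percentiles gave 38.0%, 53%, 48.0% and 42.7%. The median change of all genes in the average contrast was -0.08, and 0.05, 0.07 and 0.21 under these 3 scalings. In the average contrast 77 genes rose and 982 fell, a share of 7.27% that was 24.3%, 19.0% and 37.5% in the same order. The interferon, mitosis, DNA replication, repair, histone, oestrogen-induced and antigen presentation lists stayed lower and past the camera threshold under each of the 3 scalings.

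In all 4 knockdowns 4 genes rose and 105 fell. L1CAM, a neural cell adhesion molecule, rose 2.13-fold on average (log2 change 1.09, SE 0.107, adjusted p = 0.000162). The other 3 that rose were the unnamed transcript clusters 2968460, 3742437 and 4114368, at 2.53-, 2.12- and 1.6-fold on average, which fall outside the naming rule and are given because the count is small. Independent lists of these sizes would share 0.0557 lower genes, and unchanged groups simulated against these controls shared at most 0 genes in 20 draws and in 50 draws. Unchanged groups have few calls to share, so these draws do not show how many genes lists of the observed sizes would share through the same controls. Part of the excess may still come from the shared controls. Quantile normalization kept 74 of the 109 shared genes, with 19.2% of 99 higher, and median and 75th percentile centring put 12.7% and 29.8% higher. The average contrast had 403, 508 or 293 calls without control replicate 1, 2 or 3, and 2873 without siNELF-B replicate 2. The shared count was 31, 48 and 29 without these control arrays in turn, and 47 and 416 without siNELF-B replicates 1 and 2. It was 71, 64 and 65 without siNELF-A replicates 1, 2 and 3, 57, 54 and 58 without those of siNELF-C, and 62, 63 and 66 without those of siNELF-E. Without both siNELF-B replicates 2 and 3, 430 genes were shared, including 107 of the 109, and 2297 were called on average.

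**Figure D3:**
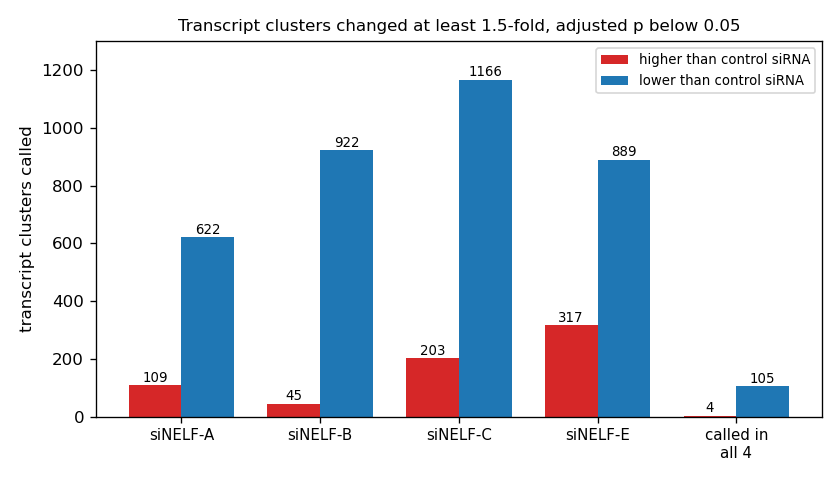
Number of transcript clusters (y axis) called higher (red) or lower (blue) than control siRNA at an adjusted p below 0.05 and at least 1.5-fold, in each knockdown and in all 4 with 1 direction (x axis). Lower genes outnumber higher ones in each knockdown, from 889 against 317 in siNELF-E to 922 against 45 in siNELF-B, although siNELF-B turns to 53% higher with arrays centred on their 75th percentiles.

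In siNELF-A cells ANXA1 rose and STAT3 fell. ANXA1, a phospholipid-binding protein, rose 9.06-fold (log2 change 3.18, SE 0.265, adjusted p = 3.26e-05), and EFNB2, a ligand of Eph receptors, rose 3.89-fold (1.96, SE 0.16, adjusted p = 2.93e-05). ANXA1 also rose 2.29-fold in siNELF-C (adjusted p = 0.0204) and fell 2.54-fold in siNELF-B (0.0222), and EFNB2 rose 1.69-fold in siNELF-E (0.0126). The scaffold LIN7A and the adhesion molecule L1CAM rose 3.46- and 3.35-fold, and the secreted LGI1 was called higher at a low level (2.033 in control, 3.71 in siNELF-A). PLAC8 rose 4.04-fold from a low 2.818 but lost its call without control replicate 1 (adjusted p = 0.154) or 3 (0.0861) or without siNELF-A replicate 1, 2 or 3 (0.108, 0.0634 and 0.0521). IGFBP5, which binds insulin-like growth factors, fell 7.1-fold (-2.83, SE 0.227, adjusted p = 2.67e-05), the glypican GPC6 fell 5.4-fold (-2.43, SE 0.275, adjusted p = 0.000401), and the signalling transcription factor STAT3 fell 5.31-fold (-2.41, SE 0.196, adjusted p = 2.93e-05). DTX3L, a ubiquitin ligase, fell 8.37-fold in siNELF-A (-3.07) and was called in every knockdown. In total 109 genes rose and 622 fell. The count was 293, 404 or 257 without control replicate 1, 2 or 3, and 370 or 307 without siNELF-A replicate 2 or 3. It was 2273 without siNELF-B replicates 2 and 3, and 1978 when only the 6 arrays compared entered the fit.

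In siNELF-B cells IFIT1, MX1, OAS2, IFIT3 and IFI6 fell 38.4-, 16.4-, 10.5-, 9.73- and 9.17-fold and kept their calls without each of the 6 arrays. VTCN1, a B7-family immune checkpoint ligand, rose 3.12-fold (log2 change 1.64, SE 0.337, adjusted p = 0.0261), and HPD, an enzyme of tyrosine breakdown, rose 2.25-fold (1.17, SE 0.219, adjusted p = 0.0178) and 1.77-fold in siNELF-C (0.0416). The apoptosis factor SIVA1 rose 2.04-fold, and the B cell antigen MS4A1 rose 2.71-fold from a low 2.806. The olfactory receptors OR52B4 and OR52N5 were called higher, but at levels too low for a fold (1.185 and 2.21 in control, 2.752 and 3.72 in siNELF-B). RWDD4, UBL3, RP2 and SLC49A4 fell 5.74-, 4.12-, 3.94- and 3.29-fold. RPF2, a ribosome assembly factor, fell 7.1-fold (-2.83, SE 0.697, adjusted p = 0.0431), although a dimmer cluster of the same symbol measured 0.64. All 11 of these genes other than the interferon genes lost their calls without control replicate 3 (adjusted p = 0.0573 to 0.156). All but RP2 lost it without control replicate 1 (0.0512 to 0.126), all but RWDD4 without siNELF-B replicate 1 (0.0542 to 0.136), 8 of them without control replicate 2 (0.0703 to 0.111), and OR52B4, OR52N5, SIVA1 and RPF2 without siNELF-B replicate 3 (0.0663 to 0.127). In total 45 genes rose and 922 fell. The count was 98, 168 and 87 without control replicates 1, 2 and 3, and 103, 7450 and 357 without siNELF-B replicates 1, 2 and 3. It was 4224 without replicates 2 and 3, which tests 1 array, and 12 when only the 6 arrays compared entered the fit, with none of the 11 among them (adjusted p = 0.35 to 0.392).

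SiNELF-C cells raised CYP1A1 and TGFB2. CYP1A1 (cluster 3633081), the xenobiotic-metabolising target of the aryl hydrocarbon receptor, rose 24.7-fold (log2 change 4.63, SE 0.262, adjusted p = 1.3e-06), from 2.90 ± 0.15 to 7.52 ± 0.14 (SD, n = 3, limma). That control level is close to the 25th percentile of all genes, so the size of this fold is uncertain. TGFB2, a transforming growth factor, rose 10.2-fold (3.35, SE 0.118, adjusted p = 1.36e-08). VTCN1, the retinoic acid-inducible receptor GPRC5A, the polyamine-degrading enzyme SAT1 and the adhesion receptor ADGRF1 rose 7.99-, 5.71-, 5.37- and 4.79-fold, and the dimmer ADGRF1 cluster measured 1.45 against 2.26 on the log2 scale. LBR, the lamin B receptor of the inner nuclear membrane, fell 5.77-fold (-2.53, SE 0.242, adjusted p = 0.000107), while its dimmer cluster measured 0.20. CYP1A1 was also called higher in siNELF-E (adjusted p = 0.0425), at levels too low for a fold (2.898 in control, 3.895 in siNELF-E). VTCN1, GPRC5A and SAT1 rose 2.97-, 2.33- and 2.96-fold in siNELF-E (adjusted p = 0.0141, 0.0122 and 0.00753), ADGRF1 rose 2.21-fold there from a low 3.039 (0.00339), and TGFB2 rose 2.21-fold in siNELF-A. All 13 genes that the rule named for siNELF-C kept their calls without each of the 6 arrays. In total 203 genes rose and 1166 fell. The count was 525, 613 or 380 without control replicate 1, 2 or 3, and 545, 423 or 686 without siNELF-C replicate 1, 2 or 3. It was 3772 without siNELF-B replicates 2 and 3, and 3781 when only the 6 arrays compared entered the fit.

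In siNELF-E cells BCAS1 rose and CDC20 and PCP4 fell, further than in the other knockdowns where they were called. BCAS1, a gene amplified in some breast cancers, rose 8.12-fold (log2 change 3.02, SE 0.2, adjusted p = 3.44e-06), and CLEC3A rose 4.53-fold. CRISP3 rose 5.08-fold from a low 2.641, and MSMB was called higher at levels too low for a fold (1.882 in control, 3.893 in siNELF-E). BCHE, butyrylcholinesterase, rose 3.77-fold (1.92, SE 0.384, adjusted p = 0.00947). GATM, the first enzyme of creatine synthesis, rose 4.06-fold but lost its call without control replicate 2 (adjusted p = 0.0557) or siNELF-E replicate 3 (0.0573). CDC20, an activator of the anaphase-promoting complex, fell 8.09-fold (-3.02, SE 0.282, adjusted p = 5.22e-05), and the calmodulin-binding peptide PCP4 fell 10.9-fold (-3.45, SE 0.154, adjusted p = 1.86e-07). BCAS1 also rose 2.01-fold in siNELF-B (adjusted p = 0.0232) and 2.77-fold in siNELF-C (0.00164), and CLEC3A rose 1.81-fold in siNELF-A (0.0357) and 3.68-fold in siNELF-C (0.000259). PCP4 also fell 3.49-fold in siNELF-B (adjusted p = 5.75e-05) and 2.25-fold in siNELF-C (0.00139), and CDC20 fell 2.16-fold in siNELF-A (0.0489) and 2.26-fold in siNELF-C (0.0268). KPNA2, an importin, fell 7.98-fold but lost its call without control replicate 1, 2 or 3 (adjusted p = 0.0868, 0.0607 and 0.13) or siNELF-E replicate 1 or 2 (0.133 and 0.0805). In total 317 genes rose and 889 fell. The count was 785 or 691 without control replicate 1 or 3, and 744, 750 or 783 without siNELF-E replicate 1, 2 or 3. It was 2348 without siNELF-B replicates 2 and 3, and 2393 when only the 6 arrays compared entered the fit.

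Direct contrasts between knockdowns asked which genes differed between the siRNA groups. Each subunit had a single siRNA label, so a difference cannot be assigned to the subunit rather than to the siRNA used. In siNELF-A the NELFA change did not pass its test, and NELFB was not analysed. CDC20 was lower in siNELF-E than in siNELF-A, siNELF-B and siNELF-C by -1.90, -2.15 and -1.84 on the log2 scale (limma adjusted p = 0.00204, 0.00125 and 0.00246). BCAS1 was higher in siNELF-E than in the same 3 by 3.23, 2.02 and 1.55 (adjusted p = 7.17e-06, 0.000207 and 0.000814), and PCP4 was lower by -3.50, -1.65 and -2.28 (2.26e-07, 0.000191 and 1.35e-05). These 9 differences kept their calls without each array of the knockdowns compared and under each scaling tried. SiNELF-E and siNELF-B differed in 1519 genes, siNELF-E and siNELF-C in 1141, siNELF-B and siNELF-A in 942, siNELF-E and siNELF-A in 891, siNELF-C and siNELF-A in 631, and siNELF-C and siNELF-B in 471.

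Scaling moved the direction of these differences. SiNELF-B had 180 genes higher and 762 lower than siNELF-A, which became 732 and 1024 after quantile normalization and 842 and 941 with arrays centred on their 75th percentiles. SiNELF-C had 353 higher and 118 lower than siNELF-B, and 728 and 530, 565 and 354, or 674 and 551 with quantile normalization, median or 75th percentile centring. SiNELF-E had 1264 higher and 255 lower than siNELF-B, and 1277 and 736 after quantile normalization or 1035 and 1139 after 75th percentile centring. Against siNELF-C it had 790 higher and 351 lower, and 959 and 759 or 854 and 947 under the same 2 settings. Against siNELF-A it had 564 higher and 327 lower, and 838 and 841 after 75th percentile centring. Single arrays mattered too. Without siNELF-A replicates 1, 2 and 3 the difference between siNELF-B and siNELF-A was 275, 199 and 610 genes, and that between siNELF-C and siNELF-A was 308, 234 and 406. Without siNELF-B replicate 1 or 2, siNELF-B differed from siNELF-A in 260 or 4687 genes, from siNELF-C in 201 or 2895 and from siNELF-E in 572 or 5769, and without replicate 3 it differed from siNELF-C in 1460. Without siNELF-C replicates 1, 2 and 3, siNELF-C differed from siNELF-A in 241, 241 and 256 genes, from siNELF-B in 146, 214 and 170 and from siNELF-E in 569, 538 and 615. Without siNELF-E replicates 1, 2 and 3, siNELF-E differed from siNELF-A in 519, 559 and 503 genes, from siNELF-B in 636, 533 and 516 and from siNELF-C in 614, 578 and 540, and without siNELF-A replicate 2 it differed from siNELF-A in 539.

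Some genes differed from control and, in the same direction, from each of the other knockdowns. They included IGFBP5, GPC6, STAT3 and ANXA1 in siNELF-A, RWDD4, UBL3, RP2 and SLC49A4 in siNELF-B, CYP1A1, TGFB2, LBR and NELFCD in siNELF-C, and CDC20, MSMB, BCHE and GATM in siNELF-E. In all there were 23 higher and 40 lower in siNELF-A, 35 and 27 in siNELF-C, and 121 and 65 in siNELF-E. SiNELF-B had 32 lower and 2 higher, the olfactory receptor OR52N5 and a cluster with several symbols, given because the count is small. Centring on 75th percentiles gave 41 higher and 116 lower in siNELF-A, 26 and 45 in siNELF-B, and 153 and 241 in siNELF-E, while median centring gave 66 higher and 92 lower in siNELF-C. The siNELF-A total of 63 was 41 without control replicate 3 or siNELF-C replicate 2, 40, 29 and 40 without siNELF-A replicates 1, 2 and 3, and 173 without siNELF-B replicate 3. The siNELF-B total of 34 was 1681 without siNELF-B replicate 2, and 21 or fewer without any 1 of the other arrays but siNELF-B replicate 3. The siNELF-C total of 62 was 111 and 288 without siNELF-B replicates 2 and 3, and 33, 31 and 35 without siNELF-C replicates 1, 2 and 3. The siNELF-E total of 186 was 328 and 359 without the same siNELF-B arrays, and 115, 104 and 101 without siNELF-E replicates 1, 2 and 3. Without both siNELF-B replicates 2 and 3, which leaves 1 siNELF-B array, the totals were 161, 643, 188 and 418 in siNELF-A, siNELF-B, siNELF-C and siNELF-E.

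Across genes, which are not independent replicates, the fold changes of 2 knockdowns correlated with r between 0.447 (siNELF-B and siNELF-E) and 0.675 (siNELF-B and siNELF-C). Unchanged groups against the same controls gave r of 0.50 to 0.503. The covariance exceeded the simulated one by 0.0658 to 0.133 in the 6 pairs. Reshuffled deviations of the arrays themselves gave wider values, with 95th percentiles of r from 0.774 to 0.838, above every observed r. The covariance lay below that percentile for siNELF-A and siNELF-B (0.121 against 0.127) and for siNELF-B and siNELF-E (0.106 against 0.117). It lay above it in the other 4 pairs, siNELF-A with siNELF-C (0.141 against 0.0992) and siNELF-E (0.115 against 0.101), and siNELF-C with siNELF-B (0.173 against 0.112) and siNELF-E (0.131 against 0.117). The values of r alone therefore do not show a common effect. The covariance of these 4 pairs passed only the 95th percentile, so some reshuffles may have given more. The deviations are also those between technical repeats.

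At the exon level, 136 probe sets of 45 genes fell in all 4 knockdowns, of which 108 belonged to 20 members of the interferon list, and 1, of RCSD1, rose and is named because the count is small. Single knockdowns had 1777 (siNELF-A), 471 (siNELF-B), 3303 (siNELF-C) and 4600 (siNELF-E) called probe sets. Relative to the rest of its gene, probe set 3549588 of IFI27, an interferon-induced mitochondrial protein, fell further in each knockdown. Its log2 usage changes were -3.70, -3.24, -4.45 and -3.65 in siNELF-A, siNELF-B, siNELF-C and siNELF-E (adjusted p = 0.000128, 0.000796, 1.57e-06 and 0.000222), and the test with each probe set's own spread called it too (adjusted p = 0.0074, 0.043, 0.00218 and 0.0185). Probe set 3549579 of IFI27 and probe sets 3432469 and 3432468 of OAS3, 3922120 and 3922126 of MX1, 3529709 of IRF9 and 2707897 of LAMP3 were higher relative to their falling genes. Probe set 3432469 of OAS3, for instance, measured 6.297 ± 0.223 in control and 6.798 ± 0.183 in siNELF-C (SD, n = 3). Probe set 3432468 itself changed by only 0.16, 0.43, 0.29 and -0.02 in siNELF-A, siNELF-B, siNELF-C and siNELF-E. That of IRF9 lay at a low 3.21 in control. Probe sets 3957820 of PATZ1, a zinc finger regulator, and 3440607 of FOXM1 were lower relative to their genes. In siNELF-C, probe set 3891281 of NELFCD was 3.95 higher relative to its gene (adjusted p = 3.55e-10; 0.0544 with its own spread), with a level of 11.2 against 10.5 in control. Where a probe set stays level while its gene falls, a probe that does not respond cannot be told apart from a change in exon use. Of the usage calls in called genes, 72 of 109, 143 of 232, 197 of 292 and 74 of 104 went opposite to the gene in siNELF-A, siNELF-B, siNELF-C and siNELF-E.

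Other probe sets had the largest usage changes of a knockdown, and some were called in further knockdowns too. Probe set 3573014 of POMT2, a protein O-mannosyltransferase, was 3.59, 3.16 and 3.04 higher relative to its gene in siNELF-A, siNELF-B and siNELF-C (diffSplice adjusted p = 1.54e-06, 4.77e-05 and 0.000121). Probe set 3795992 of the kinase YES1 was 3.74 and 3.23 higher in siNELF-B and siNELF-C (0.000308 and 0.00373). Probe set 3136039 of TMEM68 was 3.63 higher in siNELF-B (0.000302). Probe set 3079817 of PRKAG2, a subunit of AMP-activated kinase, was lower in siNELF-A, siNELF-B and siNELF-C (-3.34, -2.29 and -3.85, diffSplice adjusted p = 0.000943, 0.0494 and 4.42e-05). Probe set 3850667 of the kinetochore gene SPC24 was lower in siNELF-E (-3.71, adjusted p = 0.000207). In all, usage changed for 291, 1105, 792 and 174 probe sets in siNELF-A, siNELF-B, siNELF-C and siNELF-E, and in 1 direction in all 4 for 18 probe sets of 15 genes. These counts rest on a spread pooled over each gene, and data simulated for siNELF-C gave 200 or 358 false calls under it, with 6 or 9 shared by all 4 knockdowns. With each probe set's own spread the counts were 7, 4, 16 and 3, and IFI27 probe set 3549588 was the 1 shared. Few named usage changes were kept with their own spread, counting POMT2 only in siNELF-A, YES1 only in siNELF-B and PRKAG2 only in siNELF-C. Those kept were of IFI27 probe set 3549588 in each knockdown, IFI27 probe set 3549579 in each but siNELF-E (adjusted p = 0.0542), and MX1 probe set 3922120 in siNELF-C (0.0354).

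Exon-level counts also depended on single arrays. Called probe sets in siNELF-A, siNELF-B, siNELF-C and siNELF-E numbered 463, 70, 574 and 1844 without control replicate 1, 578, 86, 605 and 2041 without control replicate 2, and 399, 72, 392 and 1677 without control replicate 3. Without replicates 1, 2 and 3 of their own group they numbered 975, 841 and 580 in siNELF-A, 98, 68143 and 127 in siNELF-B, 807, 561 and 1138 in siNELF-C, and 1915, 2188 and 2258 in siNELF-E. The 137 shared probe sets became 53, 56 and 53 without the 3 controls in turn, 67, 702 and 77 without siNELF-B replicates 1, 2 and 3, 87, 90 and 89 without those of siNELF-C, and 89, 90 and 85 without those of siNELF-E. Usage changes numbered 100, 274, 253 and 66 without control replicate 1, 138, 347, 313 and 82 without control replicate 2, and 84, 211, 156 and 40 without control replicate 3. They numbered 155 in siNELF-A without its replicate 3, 626, 15886 and 407 in siNELF-B without its replicates 1, 2 and 3, 471, 175 and 526 in siNELF-C, and 63, 74 and 102 in siNELF-E. The 18 shared usage changes became 8, 9 and 4 without the 3 controls, 11 without siNELF-A replicate 3, 60 and 29 without siNELF-B replicates 2 and 3, 10 without each siNELF-C array, and 6, 8 and 11 without siNELF-E replicates 1, 2 and 3.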

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

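No test in this part was chosen after its result was seen. ANXA1 stood out because it differed from control in opposite directions in different knockdowns, and the contrast between those knockdowns passed limma's test. ANXA1, a phospholipid-binding protein, rose in siNELF-A (log2 change 3.18) and siNELF-C (1.20, adjusted p = 0.0204) and fell in siNELF-B (-1.35, adjusted p = 0.0222), while siNELF-E measured -0.19 (adjusted p = 0.838). SiNELF-B minus siNELF-A was -4.53 (SE 0.265, adjusted p = 7.81e-06), with the siNELF-A arrays at 7.82, 7.66 and 7.76 and the siNELF-B arrays at 2.77, 3.93 and 2.96, against 4.68, 4.31 and 4.71 in control. SiNELF-C minus siNELF-B was 2.54 (SE 0.265, adjusted p = 0.00042), with the siNELF-C arrays at 5.66, 5.65 and 5.97.

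Single arrays were not tested against the others of their group.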

How the results depend on the processing

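The settings without siNELF-B replicates 2 and 3, without the siNELF-B group, with the interquartile range of each array as a covariate and with each probe set's own spread were chosen after the values were seen, as were the 75th percentile lists, the quantile and 75th percentile pair contrasts, and the pair contrasts and correlations without single arrays. NELFCD and NELFE kept their direction and call in every setting tried, and the interferon list kept its call in every one. The lists of mitosis, DNA replication, repair, histone, oestrogen-induced and antigen presentation genes kept theirs in all but the estimated correlation. Of named genes and smaller counts over all settings, 3872 comparisons held, 376 lost a call, 44 gained one, 51 counts moved and 1 reversed. Of the values that answer a comparison, 828 held, 262 moved, 22 lost a call, 18 gained one and 1 reversed. Features called in neither setting whose sign turned count as held (98 comparisons of 30 genes and 16 of 8 lists). Where no cause is named below, the cause was not tested. Array weights did not converge and were not used, and a fit of only the 2 groups compared cannot give the average contrast.

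After quantile normalization the camera adjusted p was 0.06 for endothelial, 0.06 for leukocyte, 0.097 for pausing and 0.00179 for immediate early genes, and genes that differed numbered 1756 (siNELF-B and siNELF-A), 1393 (siNELF-C and siNELF-A), 1567 (siNELF-E and siNELF-A), 1258 (siNELF-C and siNELF-B) and 1718 (siNELF-E and siNELF-C). Median centring gave 0.0298 for immediate early genes, 1635, 1212, 1449 and 919 genes for the first 4 of these pairs, and 247 siNELF-B probe sets. With 75th percentile centring the matrix and TGF-beta list was at 0.0517, immediate early genes at 0.0185, and the 5 pairs at 1783, 1396, 1679, 1225 and 1801. Filters on dim clusters, which test fewer genes, gave 1514 siNELF-B genes, 0.0484 for cell cycle inhibitors and 0.0182 for immediate early genes above the 25th percentile. Above the median they gave 1995 siNELF-B genes, correlations of 0.41, 0.518, 0.5, 0.606, 0.387 and 0.508 (siNELF-A with B, C and E, siNELF-B with C and E, siNELF-C with E), 172 siNELF-A usage changes and 7 shared ones. At least 2-fold left 422, 494, 785 and 724 genes in siNELF-A, siNELF-B, siNELF-C and siNELF-E, 455 on average, 49 shared, and 489, 362, 505, 262, 851 and 617 between knockdowns (B and A, C and A, E and A, C and B, E and B, E and C). Treat left 61, 21, 60 and 219, with 40 on average and 13 shared. Gene values as medians of probe sets gave 395, 558, 863 and 723, with 44 shared, and turned RPL35 to -0.14 (adjusted p = 0.679). Only the 2 groups compared gave 1978, 12, 3781 and 2393, with 9 shared, since the wide spread of siNELF-B then enters its own test alone.

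With an estimated correlation the adjusted p was 0.205 for antigen presentation, DNA replication, mitosis, leukocyte, oestrogen-induced and histone genes, 0.208 for repair, 0.308 for endothelial, 0.106 for matrix and TGF-beta, 0.238 for mesenchymal and 0.688 for pausing genes. Fry gave 0.173 for endothelial, 0.0806 for leukocyte, 0.116 for mesenchymal and 0.173 for pausing genes. Without siNELF-B replicates 2 and 3, which leaves 1 siNELF-B array, there were 2273, 4224, 3772 and 2348 genes, 2297 on average and 430 shared, 11631, 14491, 31287 and 13393 probe sets with 669 shared, 2521, 5107, 5613 and 1181 usage changes with 105 shared, and 3002, 2189, 2129, 1821, 3761 and 2846 genes between knockdowns in the order above. NELFA in siNELF-A, at -0.61, then passed, heat shock genes were at 0.0349 and immediate early genes at 0.0441. Without the siNELF-B group 691 genes were shared by the other 3, 2111 were called on average, and immediate early genes were at 0.0379. The interquartile range as a covariate gave 1485 (siNELF-A), 228 (siNELF-B) and 2170 (siNELF-E) genes, 72 shared, 0.95 for endothelial, 0.611 for leukocyte and 0.81 for mesenchymal genes, and turned pausing genes upward at 0.949. The splicing index gave 10, 3, 47 and 38 usage changes with 3 shared, and each probe set's own spread 7, 4, 16 and 3 with 1 shared.

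The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.0356 to 0.0623, -0.292 to 0.107 and -0.297 to 0.203, and 2 of 15 arrays correlated best with their own number. With a replicate block there were 421 siNELF-B genes, 69 shared genes (68 of the 109), 1072, 162 and 1653 probe sets in siNELF-A, siNELF-B and siNELF-C and 80 shared probe sets. No list changed its call under the block, and the other counts moved by less than 1.5 times.

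Leaving out each array in turn gave 257 to 513 genes in siNELF-A, 87 to 7450 in siNELF-B, 380 to 686 in siNELF-C and 691 to 819 in siNELF-E, 293 to 2873 on average and 29 to 416 shared. All the lowest of these came without control replicate 3, and the highest in siNELF-B, on average and shared came without siNELF-B replicate 2. Camera adjusted p ranged from 0.0318 to 0.344 for cholesterol, 0.0488 to 0.283 for heat shock, 0.0309 to 0.232 for immediate early and 0.0326 to 0.218 for NF-kB genes, and every other list kept its call. Immediate early genes passed without control replicate 1 or 3 (0.0309 and 0.0347), siNELF-A replicate 3 (0.0324), or siNELF-B replicate 2 or 3 (0.0488 and 0.043). NF-kB genes passed without control replicate 2 (0.0326) or siNELF-B replicate 2 (0.0488), and cholesterol (0.0318) and heat shock genes (0.0488) passed without siNELF-B replicate 2. Correlations were 0.422 to 0.587 (siNELF-A and B), 0.58 to 0.665 (A and C), 0.52 to 0.594 (A and E), 0.503 to 0.71 (B and C), 0.391 to 0.502 (B and E) and 0.499 to 0.596 (C and E). Between knockdowns 199 to 4687 (B and A), 234 to 406 (C and A), 503 to 606 (E and A), 146 to 2895 (C and B), 516 to 5769 (E and B) and 538 to 615 genes (E and C) differed. NELFCD in siNELF-C was at -3.48 to -3.30, NELFA in siNELF-A at -0.75 to -0.49 and NELFE in siNELF-E at -2.63 to -2.58. Probe sets numbered 399 to 975, 70 to 68143, 392 to 1138 and 1677 to 2258 in siNELF-A, siNELF-B, siNELF-C and siNELF-E, with 53 to 702 shared, and usage changes 84 to 288, 211 to 15886, 156 to 526 and 40 to 102, with 4 to 60 shared.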

Other observations

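The tests of explanations in this part were chosen only after the result was seen, apart from the share of cell cycle genes among the lower genes and the counts over other splits of the arrays.

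Genes of several other pathways changed one by one, and a change in the average contrast need not hold in each knockdown. The p53 targets FAS, a death receptor, TP53I3 and DDB2 fell 2.43-, 1.9- and 1.72-fold in the average contrast (limma adjusted p = 0.00308, 0.00355 and 0.0124), and DDB2 lost its call without control replicate 1 (0.0798) or 3 (0.0932). MDM2 (-1.01, adjusted p = 0.0706) passed without siNELF-B replicate 2 (0.00565) or 3 (0.00492), and PLK2 measured 0.08. Of 25 p53 targets 3 fell, and 5 adjusted over the list alone (camera adjusted p = 0.264). Among 25 apoptosis regulators FAS and CASP2, an initiator caspase (1.99-fold), fell, and 4 adjusted over the list alone (camera adjusted p = 0.242), with BIRC2 and BCL2L1 at -0.42 and -0.22. Of 17 cell cycle inhibitors, CDKN2B rose 1.68-fold (adjusted p = 0.00196), and the pocket proteins RBL1 and RB1 fell 2.26- and 2.01-fold (camera adjusted p = 0.119; 2 higher and 2 lower adjusted over the list alone). TOB1 (-0.55) lay below the fold threshold but passed it without siNELF-B replicate 2, and TXNIP measured -0.44. TXNIP lay at 6.376, 6.426 and 6.14 in siNELF-A and 8.91, 8.854 and 8.785 in siNELF-E, against 8.222, 8.296 and 8.287 in control. RBL1 lost its call without control replicate 1, 2 or 3 (0.0962, 0.0772 and 0.14), and RB1 without these (0.129, 0.12 and 0.161) and also without siNELF-A replicate 3, siNELF-C replicate 2 or 3, or siNELF-E replicate 1, 2 or 3 (0.0502 to 0.0572). Of 25 hypoxia and glycolysis genes, the phosphofructokinase PFKP fell 2.1-fold (adjusted p = 0.00149) and NDRG1 rose 1.6-fold (0.00264), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.242) and LDHA and ENO1 at -0.15 and -0.12. NDRG1 lay at 4.222, 4.242 and 4.338 in siNELF-A and 6.258, 6.343 and 6.115 in siNELF-E, against 4.515, 4.443 and 4.258 in control. PHGDH, the first enzyme of serine synthesis, fell 2.36-fold (adjusted p = 0.00159), the 1 called of 29 genes of the unfolded protein and ATF4 response, and 2 adjusted over the list alone (camera adjusted p = 0.264), with CALR at -0.10. Among 19 chaperones HSPA4L fell 2.22-fold, 1 also adjusted over the list alone (camera adjusted p = 0.124), with HSPA8 and HSPB1 at -0.25 and 0.27, and it lost its call without control replicate 1, 2 or 3 (0.08, 0.0763 and 0.143). Of 21 lysosome genes the channel MCOLN1 fell 1.58-fold, 1 also adjusted over the list alone (camera adjusted p = 0.242), and lost its call without control replicate 1, 2 or 3 (0.146, 0.0516 and 0.106), with CTSA at -0.30 and PSAP at 0.44. Of 17 ribosomal protein genes RPL35 was called higher at 2.85-fold, 1 also adjusted over the list alone (camera adjusted p = 0.786), but measured -0.14 (adjusted p = 0.679) with gene values as medians of probe sets, so its direction is uncertain. It lost its call without any 1 of 12 arrays, all but siNELF-B replicates 2 and 3 and siNELF-E replicate 1 (0.0602 to 0.31), with RPL8 and RPL18 at -0.22 and -0.08.

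Signalling and marker genes were mixed, and here too an average value need not hold in each knockdown. Of 32 matrix and TGF-beta genes, TGFB2 rose 2.44-fold (limma adjusted p = 7.98e-06), while fibronectin, FN1, and TIMP1 fell 2.33- and 1.84-fold, with the same 3 adjusted over the list alone and ITGB1 and THBS1 at 0.09 and -0.18. This list was higher as a set (median 0.13, mean 0.03, camera adjusted p = 0.00333; adjusted p = 0.106 with an estimated correlation and 0.0517 with arrays centred on their 75th percentiles). FN1 lost its call without control replicate 3 (0.0833), and TIMP1 without control replicate 1, 2 or 3 (0.107, 0.0728 and 0.125). TGFB2 was highest in siNELF-C, at 6.873, 6.754 and 6.907, against 3.625, 3.839 and 3.624 in siNELF-B and 3.554, 3.408 and 3.525 in control. Of 36 pausing and elongation factors PAF1 fell 1.64-fold, 1 also adjusted over the list alone (median -0.38, camera adjusted p = 0.00258; adjusted p = 0.688 with an estimated correlation), with SSRP1 and SUPT4H1 at -0.57 and 0.00. SUPT4H1 lay at 9.364, 9.473 and 9.348 in siNELF-A and 7.718, 8.793 and 7.177 in siNELF-B, against 8.693, 8.65 and 8.728 in control. The list call was also lost after quantile normalization (0.097), by fry (0.173) and with the interquartile range of each array as a covariate, where the list turned upward (0.949). PAF1 lost its call without control replicate 1, 2 or 3 (0.113, 0.0936 and 0.132), and SSRP1 passed without siNELF-B replicate 2 (0.00725). Of 31 immediate early genes FOSL1 rose 1.54-fold and SGK1 was called lower, at levels too low for a fold (3.69 in control), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.064) and JUND and ZFP36L1 at 0.20 and -0.12. SGK1 lost its call without control replicate 1 (0.0568) or 3 (0.164), and FOSL1 without control replicate 1, 2 or 3 (0.111, 0.0612 and 0.253), siNELF-A replicate 1 or 3, siNELF-B replicate 1, siNELF-C replicate 2 or 3, or siNELF-E replicate 1 or 2 (0.0505 to 0.0605). Leukocyte, mesenchymal and endothelial markers were higher as sets (camera adjusted p = 0.00333, 0.00333 and 0.00735; adjusted p = 0.205, 0.238 and 0.308 with an estimated correlation), with medians of 0.19, 0.08 and 0.15 over 15, 19 and 13 genes. These calls were also lost with the interquartile range of each array as a covariate (0.611, 0.81 and 0.95) and by fry (0.0806, 0.116 and 0.173), and for leukocyte and endothelial markers after quantile normalization (0.06 each). In the average contrast no single marker of these 3 lists was called by limma or by treat, or adjusted over the list alone, and 1, 1 and 2 of them were higher at an unadjusted p below 0.05. CD68 and CD14 measured 0.06 and 0.25, COL1A1 and TWIST1 -0.09 and -0.16, and ENG 0.00. Nor was any called in that contrast by limma or treat among 10 basal markers, 16 cholesterol genes or 24 NF-kB genes (camera adjusted p = 0.256, 0.172 and 0.112), where 1 higher and 1 lower, 3 lower and 2 higher genes had an unadjusted p below 0.05. Adjusted over the list alone, 1 basal marker was lower. The basal median was 0.03 and its mean -0.01, and KRT23 (-0.76) passed without siNELF-B replicate 2 (0.000851) or 3 (0.0149). The cholesterol genes SQLE and DHCR7 measured -0.36 and -0.09, and the NF-kB genes NFKBIA and TNIP1 0.13 and -0.17. Against control in single knockdowns, limma called members of 5 of these 6 lists that the average contrast did not. KRT23 was called lower in siNELF-A and siNELF-B (adjusted p = 0.00267 and 0.0455) and TRIM29 higher in siNELF-C and siNELF-E (0.00674 and 0.000978). INSIG1 was called lower in siNELF-B and siNELF-C (0.0455 and 0.00166), PMVK lower in siNELF-B (0.0341), and FDPS and SQLE lower in siNELF-C (0.0114 and 0.0226). MS4A1 and BCL3 were called higher in siNELF-B (0.0236 and 0.0414) and COL5A2 in siNELF-C (7.08e-05). These single-knockdown calls were named after their values were seen. Camera in single knockdowns put the cholesterol list lower in siNELF-B and siNELF-C (medians -0.49 and -0.67, adjusted p = 0.0225 and 0.000292). It was higher in siNELF-E (0.30, adjusted p = 0.0426), so its average mixes opposite changes. Lysosome genes were lower in siNELF-B (0.00757) and cell cycle inhibitors higher in siNELF-E (0.0123). With an estimated correlation none of these list results passed (0.547, 0.418, 0.898, 0.538 and 0.084, in this order). Some lists share genes, 16 in all.

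The fall of interferon-stimulated genes in all 4 knockdowns was weighed first. Differences in array spread are argued against, since the list kept 81.5% of its median change with the interquartile range of each array as a covariate. A raised level in the control culture, or one induced by the control siRNA, may explain the fall, since the list's medians varied little between knockdowns (SD 0.142 of their mean size). Loss of the NELF complex stays open too, since the change in siNELF-A was larger than in siNELF-E by -0.35 while the NELFA change itself did not pass its test. These cannot be told apart here, because every comparison used the same 3 controls and no untransfected cells were analysed.

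SiNELF-B replicate 2 lay close to the controls, but control RNA under a siNELF-B label is argued against, because the called interferon-stimulated genes lay at -1.63 from the control mean on that array. Control RNA mixed into the siNELF-B RNA is also argued against, since those genes allow 8.16% of control RNA while the mitosis genes would need 81.7%. A siNELF-B culture or RNA of its own with a smaller effect may account for the array, as 82.4% of the genes lower in siNELF-A, siNELF-C and siNELF-E lay below all 3 control arrays there. Those genes were chosen against the same controls, and a control array held out of that choice lay below the other 2 for 13.7% to 75% of them, against 94% to 98% for siNELF-B replicate 2. The series text calls the repeats technical, which would leave the handling of the RNA or of the array as the place where such a difference arose. Array spread was not tested for this pattern. The interquartile range was 4.02 on replicate 2, within the 3.95 to 4.12 of the controls, and 3.57 and 3.12 on replicates 1 and 3. With that range as a covariate, mitosis genes called lower in siNELF-B went from 4 to 0. Replicates 1 and 3 may therefore be the unusual arrays, which cannot be told apart here from a smaller effect in replicate 2.

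Many more genes fell than rose. Differences in array spread could account for part of this, since the share of higher genes in the average contrast went from 7.27% to 24.3% after quantile normalization, which still left more genes lower. Members of the 4 cell cycle lists made up 10.3% of the lower genes, but this share was no test of the fall of cell cycle genes, because the 146 members could at most have made up 14.9%. Outside these lists 881 genes fell and 77 rose, so the fall of the members does not account for the excess alone, and how far cell cycle genes outside the lists add to it was not tested.

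Other splits of the arrays were counted for each test. For a knockdown against control there are 10 splits of the 6 arrays, too few for a share under 0.05. The real split gave 731, 967, 1369 and 1206 genes in siNELF-A, siNELF-B, siNELF-C and siNELF-E against highest other values of 0, 1, 0 and 0, so that 1 of 10 splits reached the real count in each. For probe sets the real values were 1777, 471, 3303 and 4600 against 0, 2, 0 and 0, again 1 of 10. For exon usage they were 291, 1105, 792 and 174 against 19, 1623, 18 and 14. In siNELF-B 3 of the 10 splits gave as many usage changes, the highest setting siNELF-B replicate 2 with control replicates 1 and 3, a structure that follows the closeness of that array to the controls. Between knockdowns the real values were 631, 891, 471, 1519 and 1141 for siNELF-C and siNELF-A, siNELF-E and siNELF-A, siNELF-C and siNELF-B, siNELF-E and siNELF-B, and siNELF-E and siNELF-C, against 0, 0, 1, 1 and 0. For siNELF-B and siNELF-A 2 of the 10 splits gave as many genes, 942 against 1835 when siNELF-B replicate 2 changed places with siNELF-A replicate 3.

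Regroupings of all 15 arrays, 100 drawn with the real one included, allow smaller shares. The series text calls the repeats technical, so these regroupings and splits test only how single arrays fall into groups, and a chance difference between the cultures behind the groups is not excluded by any of them. Chance among the arrays was excluded for the 109 shared genes (1 of 100, highest other 16), the 137 shared probe sets (1 of 100, highest other 96), the interferon list (1 of 100, with a -log10 p of 32.3 against 17.9) and, less clearly, for the 1059 genes of the average contrast and the mitosis list (2 of 100 each). A regrouping with siNELF-B replicates 1 and 3 and siNELF-C replicate 2 as control called 3219 genes. Those arrays had the narrowest interquartile ranges of all (3.57, 3.12 and 3.61). The first principal component, the main axis of variation between arrays, held 38.5% of the variance and correlated with that range (r = -0.989). Another regrouping, with siNELF-C replicate 2 and siNELF-E replicates 1 and 2 as control, gave the mitosis list a -log10 p of 39.1 against 29.1. The mitosis medians of those arrays were low themselves (-1.48, -2.39 and -2.01). Chance among the arrays was not excluded for the number of lists called, 12 (13 of 100, highest other 14). Nor was it excluded for the 18 shared usage changes (5 of 100, highest other 381, with siNELF-B replicates 1 and 3 and siNELF-C replicate 2 as control).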
